A study of Saccharomyces cerevisiae with 320 samples.

How the data were processed

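The samples were polyadenylated RNA of 22 yeast deletion strains, collected at 8 times of growth in pure nitrogen gas (0, 5, 10, 30, 60, 120, 180 and 240 min). The labels give an S288C background, mating type MATa, with a repaired HAP1 gene. The deposited tables hold counts, whole numbers of reads per annotated gene, as the authors made them. Per the labels' protocols, cells were filtered and frozen, RNA was isolated with a Qiagen RNeasy kit after bead lysis, polyadenylated RNA was captured with oligo-dT, and libraries were made with a TruSeq RNA kit. Per the submitters' processing notes, the tools were TopHat2 and HTSeq and the genome build was R64; their versions and the counting options, strand included, were not given in the sources used here. In 288 tables, reads aligned to several places were reported by the counter on a separate line and not given to a gene. There, members of families with near-identical copies (PAU, TIR, HXT and ribosomal protein genes) are undercounted to an unknown degree. The 32 tables of the upc2, mga2, ecm22 and upc2 ecm22 strains carried no such line, so how their counts treated these reads is not shown. Values of such families are uncertain in all tables. Overlapping and antisense genes are uncertain for the same reason of unknown strand use.

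Of the 7140 features per table, 6048 were matched by systematic name to the R64 reference annotation, which gave gene names, coordinates and lengths. Of the 320 tables, 288 also carried 5 summary lines that name no gene, and 32 carried none. Those lines were left out of library sizes and tests. For every 100 reads given to genes they held a median of 116.3 multiply aligned reads (53.4 to 246.8), 6.2 reads outside features (4.4 to 11.1) and 0.3 ambiguous reads (0.3 to 0.5). Ribosomal RNA features held at most 0.107% of gene reads, and the 10 most abundant genes of a library held 7.9% to 19.1%.

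The sample names of 18 strains begin with NH and those of 4 strains (upc2, mga2, ecm22 and upc2 ecm22) begin with SW. Each NH library was deposited as a pair of tables, from 2 sequencing lanes per the labels' protocols. Over genes with at least 20 reads, the chi-square per degree of freedom of the 144 lane pairs lay between 0.948 and 1.046, and 10 pairs had an unadjusted p under 0.05 (smallest p = 0.00799, 0.535 after Benjamini-Hochberg adjustment over the pairs). No pair was identical. The lanes of a pair thus differed by no more than sampling noise, and were summed and counted as 1 library. For comparison, hap2 against hap3 libraries of the same time gave 53.8 to 126.5. This left 176 libraries, 1 per strain and time. No library of an undeleted strain was analysed here. With 1 library per strain and time, different strains that share a genotype feature served as replicates, so p-values measure only the spread between these strains, and nothing in the labels says that libraries of a strain came from separate cultures.

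Gene reads per library ranged from 3.93 M to 18.22 M (median 11.27 M), with medians of 12.0 M in NH and 6.95 M in SW libraries. At the lowest depth, the exact (Clopper-Pearson) 95% interval was 7.0 to 13.6 for a level of 10 CPM (read counts scaled to the same total in each library), 90.3 to 110.3 for 100 CPM and 968.9 to 1031.6 for 1000 CPM. Such intervals cover counting error only.

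Tests used edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test with robust dispersions, TMM factors), on genes with at least 10 reads in at least 5 libraries of a fit, and adjusted p-values are Benjamini-Hochberg values over the genes of the contrast. Every adjusted p of a gene printed below is of that kind unless DESeq2 (1.42.0) is named. CPM values divide by all gene reads of a library. Standard errors of log2 fold changes are the size of the fold divided by the root of its F statistic. The time course was tested at 5, 30, 120 and 240 min against 0 min, with the 22 strains as replicates and the strain as a block. A gene was called at an adjusted p under 0.05 and an absolute log2 fold change of at least 1. Strain effects at 0 min came from 1 fit of 22 libraries, with terms for loss of the HAP complex (hap2, hap3, hap4, hap5 and the quadruple deletion), rox1, mot3, hap1, upc2, ecm22 and the SW prefix, and a contrast between 5 strains lacking subunits of the DSC ubiquitin ligase and 3 strains lacking TPA1, ETT1 or both. Those 8 strains served as the reference for the HAP complex, rox1, mot3 and hap1 terms, and upc2 and ecm22 were compared within the SW strains, where mga2 had no term of its own and so belongs to the compared strains of both. Their effect on the response to hypoxia was the interaction of the same terms with late hypoxia (the reads of 120, 180 and 240 min summed per strain) against 0 min, with the strain as a block. These were called at an adjusted p under 0.05. The only strain lacking MGA2 had no replicate, so no p-value is given for it. Its genes were taken by size, at least 1 log2 unit beyond the range of the other strains at both 0 min and late, with a pseudocount of 0.5.

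Before the data were examined, 20 gene lists were fixed: ergosterol synthesis, anaerobic cell wall and sterol uptake, PAU family, Rox1-repressed hypoxic, respiratory chain, ATP synthase, TCA cycle, heme synthesis, oxidative stress defence, fatty acid synthesis, ribosome biogenesis, ribosomal protein, environmental stress, glycolysis and fermentation, hexose transport, iron regulon, ER folding and degradation, amino acid synthesis, a-mating-type and alpha-mating-type. Each was tested with camera (limma 3.58.1), which compares a list with all other genes, at a preset correlation of 0.01 and again with an estimated correlation, and adjusted over the 20 lists of a contrast. The rule for named genes was fixed at the same time. For the time course it took the 10 largest rises and 10 largest falls at 240 min among called genes with a mean of at least 10 CPM and the same sign in all 22 strains. For strain terms it took up to 8 rises and 8 falls among called genes of at least 10 CPM, with every carrying strain on the same side. From each list it took the called members with the largest changes, up to 4, and 29 regulators and hypoxic marker genes were always eligible. The tests, the groups and the alternatives named last were also set before the data were examined.

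The 16 deleted genes were examined in every library. A library went against its label where a deleted gene reached at least 10% of its median in the strains keeping it at that time, or where a gene that should be present was at most 5% of it. These thresholds, the fits without the libraries that failed them, the fit that also left out the 180 and 240 min libraries of hap2 hap3 hap4 hap5, the correction for gene length and the fits at 10, 60 and 180 min were chosen after the data were seen. Library labels were kept as given, and no library was moved to another group.

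The procedures were tested on simulated counts with known changes. Of genes changed by 3 log2 units at 0 min, 100% were recovered for the HAP complex term, 98% for rox1, 99% for hap1 and 90% for upc2 (5808 genes). At 1 log2 unit the shares were 84%, 38%, 47.5% and 21%. For the response they were 92%, 93.9%, 88% and 87% at 3 log2 units, and 66.3%, 23.2%, 32% and 21% at 1 (6317 genes). False calls at 0 min were 15 of 198 for the HAP complex, 9 of 145 for rox1, 4 of 149 for hap1 and 4 of 115 for upc2, so the first 2 lay above the nominal share. For the response they were 6 of 163, 4 of 120, 5 of 125 and 6 of 114, the last also above it. At 240 min of the time course 98% of changes of 1.5 log2 units were recovered, with 1 false call of 197 (6142 genes), and the list test found 5 of 5 moved lists and no other (6186 genes). Simulated counts were drawn independently for each gene and library, with no wrong label or length bias added. These shares therefore need not hold where the real libraries have such faults. Alternatives set beforehand were DESeq2, RLE factors, no filter on low counts, the lane 1 tables alone, no strain block, NH or SW strains alone, 240 min alone as late hypoxia, and leaving out each strain in turn. Data handling used Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.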

Results

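RNA was measured in 22 yeast strains, each lacking 1 or more genes, at 0, 5, 10, 30, 60, 120, 180 and 240 min after a switch to pure nitrogen gas. The design text of the series asks how the transcriptional response to loss of oxygen unfolds and how it depends on the deleted genes. Of the 176 libraries, 144 came from 18 strains of the NH sample prefix and 32 from 4 strains of the SW prefix, with 1 library per strain and time. NH libraries held 5.21 to 18.22 M gene reads and SW libraries 3.93 to 9.33 M. The deleted genes encode the oxygen- and heme-linked regulators Hap1, Rox1, Mot3 and the Hap2/3/4/5 complex, the sterol regulators Upc2 and Ecm22, and Mga2, an activator of the fatty acid desaturase gene OLE1. Other strains lack subunits of the DSC ubiquitin ligase (DSC2, DSC3, TUL1 for dsc1 and UBX3 for dsc5) or TPA1 and ETT1. No undeleted strain was analysed here, so every comparison is between deletion strains.

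In 157 libraries the deleted genes went with the label. There, transcripts of deleted genes reached at most 4.96 CPM (read counts scaled to an equal library total) for UPC2, 3.22 for ETT1, 2.51 for HAP1 and 1.77 for DSC2, and 1.71 or less for the other 12, against medians in strains keeping them of 138 CPM for UPC2, 242 for HAP1 and 401 for MGA2. The 19 others went against it. All 8 libraries labelled dsc1 held TUL1 at 40.4 to 84.7 CPM, while ROX1 was at most 0.21 CPM and MOT3 at most 0.41 CPM. All 8 libraries labelled rox1 mot3 held TUL1 at no more than 0.65 CPM, ROX1 at 0.66 to 254 CPM and MOT3 at 7.51 to 142 CPM. ROX1 lies on chromosome XVI (R64, 679693 to 680799), MOT3 on chromosome XIII (409154 to 410626) and TUL1 on chromosome XI (371829 to 374105).

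Among the single libraries, the 60 min library labelled hap1 held HAP1 (chromosome XII, 646415 to 650923) at 323 CPM (exact 95% interval 313 to 332) and HAP2 (chromosome VII, 52731 to 53528) at 0.15 CPM (0.02 to 0.55). The 60 min library labelled hap2 held HAP1 at 1.79 CPM (0.98 to 3.0) and HAP2 at 8.82 CPM (6.86 to 11.2). In the 240 min library labelled hap1, HAP1 stood at 60.8 CPM (56.5 to 65.4), 15.9% of its level in strains keeping it, and HAP2 at 0.33 CPM (0.09 to 0.84). Comparisons below kept every label as given and were repeated without these 19 libraries, of which 2 are at 0 min.

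**Figure D1:**
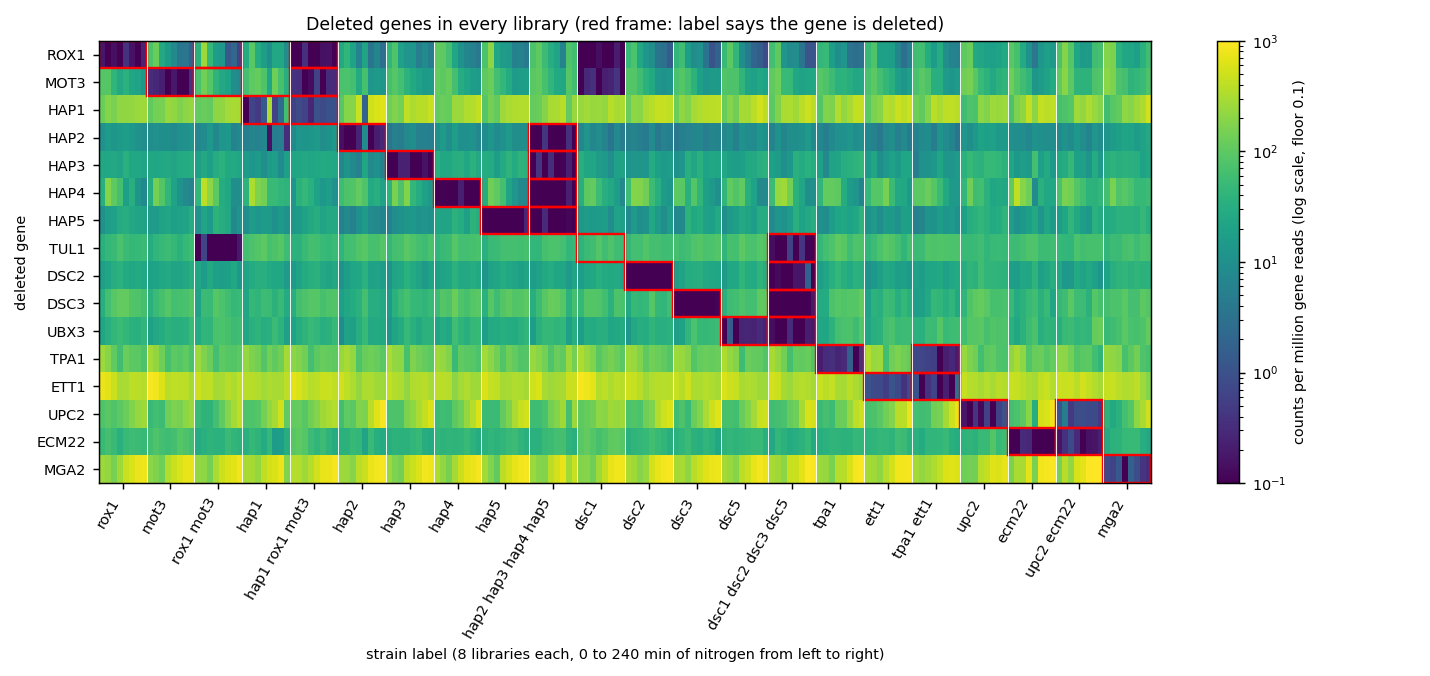
Heat map of the level in CPM (colour, log scale with a floor of 0.1) of each deleted gene, 1 gene per line of the map, in every library, grouped by strain label with the 8 times from left to right; a red frame marks genes that the label gives as deleted. ROX1 and MOT3 are near 0 in the libraries labelled dsc1 and present in those labelled rox1 mot3, where TUL1 is near 0.

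Anaerobic cell wall and sterol uptake genes rose over 240 min. DAN1, a cell wall mannoprotein gene (chromosome X, 708811 to 709707), went from 135 ± 376 CPM (SD, n = 22 strains) to 2985 ± 1536 CPM, a log2 fold change of 7.69 (SE 0.778, adjusted p = 2.19e-09). TIR1, of the same kind (chromosome V, 175248 to 176012), went from 304 ± 711 to 4877 ± 2784 CPM, with 6.08 (SE 0.662, adjusted p = 6.87e-09). TIR4 rose by 5.42 and TIR3 by 4.80, and HES1, for an oxysterol-binding protein, went from 9.0 ± 7.6 to 938 ± 470 CPM. All 8 tested members of the list rose at 240 min (camera adjusted p = 1.28e-05; adjusted p = 0.262 with an estimated correlation) and 6 at 120 min. At 30 min 1 of 8 rose, and DAN1 stood at 312 ± 789 CPM with a log2 value of 0.18. Of the PAU family, close relatives that share reads, 13 of 14 rose at 240 min (adjusted p = 3.28e-06; adjusted p = 0.262 with an estimated correlation). PAU2 went from 0.8 to 25.3 CPM and PAU13 from 0.1 to 16.5 CPM, and PAU9 from 0.0 to 16.8 CPM. The counts of called list members were the same adjusted over the list alone at every time.

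Of 8 Rox1-repressed hypoxic genes, 5 rose at 240 min (adjusted p = 0.00353; adjusted p = 0.262 with an estimated correlation). ANB1, the hypoxic form of translation factor eIF5A (chromosome X, 524908 to 525381), rose by 5.49 (SE 0.663, adjusted p = 4.97e-08) and was higher in 19 of 22 strains. HEM13, a heme synthesis gene (chromosome IV, 546642 to 547628), rose by 3.91, from 178 ± 312 to 1593 ± 642 CPM, and COX5B, the hypoxic cytochrome oxidase subunit, by 2.95 in all 22 strains. AAC3 rose by 2.64 and HMG2 by 1.48. CYC7 was called at 5 min (2.03) and 30 min (2.25) and stood at 0.52 at 240 min. OLE1 (chromosome VII, 398628 to 400160) fell by 2.52 at 30 min (SE 0.324, adjusted p = 1.25e-07), from 3328 ± 1433 to 807 ± 619 CPM, and at 240 min stood at 7754 ± 2846 CPM, a log2 value of 0.99, under the size threshold. Of the heme synthesis list 3 of 8 rose at 240 min (adjusted p = 0.106), with HEM14 at 1.97 and HEM15 at 1.46.

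Respiratory genes fell from 120 min on. In the respiratory chain list 17 of 22 fell at 240 min (adjusted p = 0.000344; adjusted p = 0.464 with an estimated correlation), as many as at 120 min, while at 30 min 6 fell and 3 rose. CYC1, the aerobic cytochrome c (chromosome X, 526335 to 526664), fell by 5.45 (SE 0.652, adjusted p = 4.13e-08), COX5A by 3.11, COX4 by 2.86 and CYT1 by 2.86. The succinate dehydrogenase genes SDH1 (1.51) and SDH2 (1.46) rose at 30 min. TCA cycle genes rose at 30 min, 6 of 10 (adjusted p = 4.72e-05; adjusted p = 0.184 with an estimated correlation), with CIT1 at 2.89; 2 of 10 were called at 240 min (0.0072, and adjusted p = 0.262 with an estimated correlation). ATP synthase had 1 of 13 down at 240 min, ATP20 with -1.13 (adjusted p = 0.109 for the list).

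Sterol genes of the ergosterol pathway fell early. At 30 min 14 of 25 fell (adjusted p = 0.000226; adjusted p = 0.631 with an estimated correlation), and at 240 min 6 fell and 1 rose (adjusted p = 0.12 for the list). HMG1 fell by 2.70 at 240 min and ERG5 (chromosome XIII, 300869 to 302485) by 4.27, and ERG3 by 1.61. ERG11, the target of azole drugs (chromosome VIII, 120091 to 121683), fell by 1.43 at 30 min and by 1.15 at 240 min (SE 0.225, adjusted p = 6.39e-05). In fatty acid synthesis, ACC1 rose by 1.52 and FAA1 fell by 3.31 at 240 min (adjusted p = 0.392 for the 9 members). The regulator genes moved too, UPC2 up by 2.61, HAP1 by 1.73 and MGA2 by 1.42, ROX1 down by 3.46 and MOT3 by 2.13. HAP4 rose by 1.57 at 5 min and fell by 1.93 at 240 min.

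Environmental stress genes rose early. At 5 min 14 of 20 rose (adjusted p = 4.72e-13; adjusted p = 0.578 with an estimated correlation), and all 20 rose at 30, 120 and 240 min. The list passed with an estimated correlation at 120 min (adjusted p = 0.00561), but at 30 and 240 min adjusted p = 0.127 and adjusted p = 0.227 with an estimated correlation. The glycogen synthase gene GSY1 rose by 3.58 at 5 min and by 4.39 at 30 min, and TSL1, for trehalose synthesis, by 3.19 and 4.85. HSP12 stood at -0.15 at 5 min and rose by 5.63 at 30 min. RTC3, of unclear function, rose by 4.82 at 240 min after 5.48 at 30 min. Ribosome biogenesis genes moved the other way. All 24 fell at 30 min (adjusted p = 1.76e-22; adjusted p = 0.127 with an estimated correlation), 22 at 240 min and 3 at 5 min. The helicase gene DBP2 fell from 1756 ± 658 to 37.3 ± 15 CPM at 30 min (log2 fold change -5.66) and was at 198 ± 234 CPM at 240 min, and NSR1, for a nucleolar protein, fell by 4.81 at 30 min and stood at -3.13 at 240 min. Ribosomal protein genes, many of which share reads with a copy, had 9 of 132 down at 30 min and 6 at 240 min (adjusted p = 1.16e-07; adjusted p = 0.672 with an estimated correlation). BSC1, on chromosome IV (384601 to 385587), fell by 4.72 at 240 min and PRM7 by 4.50.

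Other lists moved in part. Glycolysis and fermentation genes rose at 30 min, 4 of 17 (adjusted p = 0.000254; adjusted p = 0.562 with an estimated correlation), with TDH1 at 4.14 and ENO1 at 2.52, and 1 at 240 min (adjusted p = 0.482). Of the hexose transporters, close relatives that share reads, HXT3 fell by 3.08 and HXT1 by 2.35 at 30 min while HXT5 rose by 3.65 (2 rose and 4 fell of 7, adjusted p = 0.57). Iron regulon genes, for iron uptake, fell, 6 of 15 at 120 min (adjusted p = 9.93e-05; adjusted p = 0.136 with an estimated correlation) and 4 at 240 min, FET3 by 3.64 and FRE1 by 3.03. In oxidative stress defence, YHB1 fell by 3.63 and GPX2 by 2.45 while TSA2 rose by 4.50 at 240 min (3 rose and 5 fell of 13, adjusted p = 0.707). ER folding and degradation genes rose, 3 of 13 at 240 min (adjusted p = 0.00309; adjusted p = 0.29 with an estimated correlation), with EUG1 at 1.66 and KAR2 at 1.10. Amino acid synthesis had 3 of 15 down (adjusted p = 0.218), LYS20 by 1.26. Median, mean and test differed in sign for oxidative stress defence at 30 min (median 0.09, mean -0.09, adjusted p = 0.879), hexose transport at 5 min (0.07 and -0.07) and a-mating-type genes at 120 min (0.06 and -0.03), with the test on the lower side. No a-mating-type (6 tested, adjusted p = 0.355) or alpha-mating-type gene (3 tested, adjusted p = 0.701) was called.

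By edgeR's quasi-likelihood test, 207 of 6153 genes were called at 5 min (136 rose and 71 fell), 1287 of 6169 at 30 min (601 and 686), 815 of 6153 at 120 min (430 and 385) and 1284 of 6186 at 240 min (657 and 627). Without the 19 conflicting libraries the counts were 191, 1264, 807 and 1340. In the 4 SW strains alone they were 37, 964, 415 and 546. At 240 min 992 of the called genes had at least 10 CPM and 536 of them moved the same way in all 22 strains, 292 up and 244 down.

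**Figure D2:**
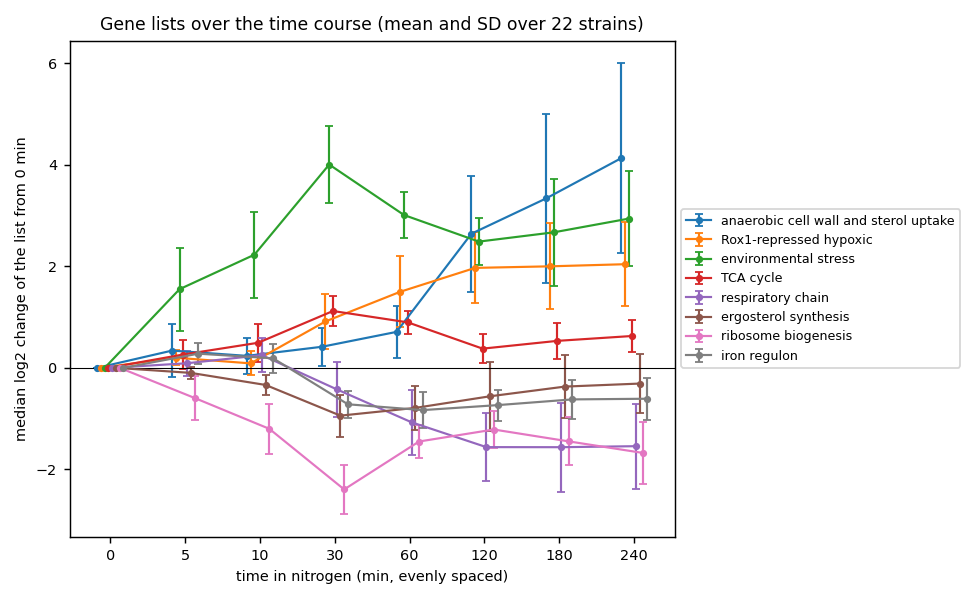
Median log2 change from 0 min of 8 gene lists (vertical axis) against time in nitrogen in min, evenly spaced (horizontal axis); points are means over the 22 strains and bars are SDs. The environmental stress list is highest at 30 min, where ribosome biogenesis is lowest, and the anaerobic cell wall and sterol uptake list is highest at 240 min.

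The rox1 comparison asks which genes the repressor Rox1 holds down with oxygen present. Without the conflicting libraries, ANB1 was at 677 ± 114 CPM at 0 min (SD, n = 2 strains lacking ROX1) against 8.4 ± 7.3 CPM (n = 7), a log2 difference of 5.41 (SE 0.491, adjusted p = 9.07e-06). The 2 strains were rox1 and hap1 rox1 mot3, so their mean levels also reflect loss of HAP1 and MOT3 in the latter. The log2 differences are adjusted for the other terms of the fit and need not match the ratio of the mean levels. HEM13 was higher by 3.86 (1034 ± 334 against 56.1 ± 17.6 CPM, SE 0.308, adjusted p = 3.76e-06), COX5B by 3.22, AAC3 by 2.44 and HEM14 by 1.40. TIR1 was higher by 4.01 and the cell wall gene CWP1 by 1.91, and the iron uptake gene FET3 was lower, with -1.46. In this fit 5 of 8 Rox1-repressed genes were called, 6 adjusted over the list alone (adjusted p = 1.32e-35; adjusted p = 0.000369 with an estimated correlation), and 2 of 8 heme synthesis genes, HEM13 and HEM14 (adjusted p = 2.06e-08; adjusted p = 0.0114 with an estimated correlation).

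In the fit over all libraries the rox1 term rests on 3 strains, and 1 of them is the course labelled rox1 mot3, which kept ROX1, while the reference holds the course labelled dsc1, which lacked it. There, no Rox1-repressed gene was called by edgeR over all genes and 6 of 8 adjusted over the list alone (adjusted p = 1.23e-10; adjusted p = 0.0131 with an estimated correlation), and 0 of 15 iron regulon genes were called, 7 adjusted over the list alone, on the lower side (adjusted p = 1.07e-15; adjusted p = 0.0131 with an estimated correlation). The iron regulon call was lost without the conflicting libraries, with 1 of 15 called, 5 adjusted over the list alone (adjusted p = 6.01e-09; adjusted p = 0.12 with an estimated correlation). Only the sphingolipid gene SUR2 (chromosome IV, 1056551 to 1057600) was called, at 428 ± 182 against 198 ± 45.2 CPM, higher by 1.44 (SE 0.204, adjusted p = 0.00929). All in all 1 of 5855 genes was called over all libraries, with 260 at an unadjusted p under 0.05, and 35 of 5825 without the conflicting libraries, 32 of them higher. Across genes, which are not independent replicates, the log2 differences over all libraries went down with gene length (Spearman rho -0.326), and no length trend was removed for this term. The count over all libraries was 2 without mot3, 0 without rox1, 9 without rox1 mot3 and 5 without dsc1. The change from 0 min to late hypoxia differed for 0 of 6336 genes by edgeR (90 at an unadjusted p under 0.05; 1 by DESeq2) and for 2 without the conflicting libraries, SUR2 (-1.56, adjusted p = 0.00586) and YHK8 (-2.04, adjusted p = 0.0117); without rox1 mot3 alone it was 1.

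Mot3, a second repressor of hypoxic genes, was set against the same reference. Without the conflicting libraries, DAN1 stood at 847 ± 880 CPM at 0 min (n = 2) against 16.4 ± 23.7 CPM (n = 7), a log2 difference of 5.05 (SE 0.983, adjusted p = 0.0147). The 2 strains were mot3 and hap1 rox1 mot3, so their mean levels also reflect loss of HAP1 and ROX1 in the latter. As for rox1, the log2 differences are adjusted for the other terms of the fit. TIR3 (chromosome IX, 333727 to 334536) was at 1295 ± 939 against 29.8 ± 20 CPM, 4.14 (SE 0.334, adjusted p = 2.11e-06). The sterol importer gene PDR11 was higher by 1.90, ANB1 by 2.88 and AAC3 by 1.96. Agglutinin genes of mating cells were higher as well, AGA1 by 2.25 and AGA2 by 1.97, while ARO10, for amino acid breakdown, was lower, with -3.19. Among the lists, 6 of 8 anaerobic cell wall genes were called, 8 adjusted over the list alone (adjusted p = 3.31e-26; adjusted p = 9.23e-05 with an estimated correlation). Of the a-mating-type genes 2 of 6 were called, 3 adjusted over the list alone (adjusted p = 3.4e-05; adjusted p = 0.0281 with an estimated correlation).

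Over all libraries, where the mot3 term includes the library labelled rox1 mot3, in which MOT3 was present, 3 of 5855 genes were called, with 467 at an unadjusted p under 0.05. FUS1, a mating gene, was at 28.8 ± 11.7 against 14.8 ± 3.2 CPM (log2 difference 1.77, adjusted p = 0.0149); FIG1 and PRM1, also mating genes, were chosen after their values were seen. The a-mating-type list had 0 of 6 called and 4 adjusted over the list alone (adjusted p = 5.96e-07; adjusted p = 0.00299 with an estimated correlation), and the anaerobic cell wall list 0 and 2 of 8 (adjusted p = 1.37e-05; adjusted p = 0.522 with an estimated correlation). Without the conflicting libraries the count was 61 of 5825, 53 of them higher. Over all libraries, rho of the log2 differences with gene length across genes was -0.435, with no length trend removed. Leaving out 1 strain of all libraries gave 5 without hap4, 0 without mot3, 16 without rox1, 12 without rox1 mot3 and 27 without dsc1. No response differed with mot3 by edgeR (151 genes at an unadjusted p under 0.05; 0 by DESeq2), with or without the conflicting libraries.

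Hap1 activates respiratory and sterol genes when heme is present. At 0 min the 2 strains lacking HAP1 (hap1 and hap1 rox1 mot3) had CYC1 at 4.0 ± 3.0 CPM against 38.6 ± 22 in the 8 reference strains, a log2 difference of -4.20 (SE 0.521, adjusted p = 0.000306). The nitric oxide dioxygenase gene YHB1 was at 196 ± 143 against 1982 ± 275 CPM (-3.42, adjusted p = 0.000131), the lipid droplet gene PLN1 at 15.2 ± 2.4 against 109 ± 18.1 CPM (-2.97, adjusted p = 4.42e-06), and CYT1 (-2.16) and RIP1 (-1.63) were lower too. Of the respiratory chain 3 of 22 were called lower, 6 adjusted over the list alone (adjusted p = 1.66e-15; adjusted p = 0.0142 with an estimated correlation). With the conflicting libraries left out, that last value became adjusted p = 0.0828 with an estimated correlation. In the ergosterol list 1 of 25 was called lower, ERG12 with -1.26, and 15 lower and 1 higher adjusted over the list alone (adjusted p = 1.02e-15; adjusted p = 0.0689 with an estimated correlation). The reference includes the library labelled dsc1, which lacked ROX1 and MOT3. Altogether 8 of 5855 genes were called, and 22 of 5825 without the conflicting libraries.

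Over hypoxia, the change from 0 min of respiratory and sterol genes was higher in the strains labelled as lacking HAP1 than in the reference. Their late sum includes the 240 min library labelled hap1, in which HAP1 was at 15.9% of its usual level and HAP2 at 0.33 CPM. That library had a slope of 0.346 against the changes of the other strains, the lowest of all strains at 240 min. The values below include it. Of 930 values of 30 named genes for this response under the alternatives, 845 kept direction and side of the threshold, 85 kept only the direction and 0 reversed. Those alternatives include the fit without the conflicting libraries. This library was not left out alone. Without the conflicting libraries, this one among them, 127 genes differed. CYC1 was at 12.7 ± 2.5 CPM in late hypoxia against 0.7 ± 0.7 CPM in the reference, so that the change from 0 min differed by 8.73 (SE 1.065, adjusted p = 0.000108). ERG5 stood at 280 ± 148 against 11.7 ± 5.7 CPM (difference of changes 6.29, adjusted p = 2.99e-05), the NADH dehydrogenase gene NDE1 at 453 ± 253 against 27.5 ± 5.0 CPM (4.71), and HMG1 at 241 ± 34.2 against 74.7 ± 4.3 CPM (3.52). ERG3 differed by 3.10 (2181 ± 109 against 428 ± 158 CPM), ERG11 by 2.97 (7785 ± 3270 against 1397 ± 470 CPM) and the superoxide dismutase gene SOD2 by 2.90. Lower responses were seen for TIR4 (-4.37), the ribonucleotide reductase gene RNR3 (-2.73), the sterol importer gene AUS1 (-2.22) and the iron transporter gene FET4 (-1.92). At 0 min TIR4 was already at 726 ± 939 CPM in these 2 strains against 122 ± 201 CPM, with 62.2 CPM in hap1 and 1390.3 CPM in hap1 rox1 mot3. FET4 was higher at 0 min in the rox1 comparison without the conflicting libraries, at 220 ± 50.4 against 77.3 ± 19.8 CPM. In the present fit the rox1 and mot3 terms include the conflicting courses. Loss of HAP1 is therefore not cleanly separated from loss of ROX1 and MOT3 in these lower responses.

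In that response 16 of 22 respiratory chain genes were higher, 18 adjusted over the list alone (adjusted p = 5.65e-45; adjusted p = 0.000394 with an estimated correlation). So were 14 of 25 ergosterol genes, 22 with 1 lower adjusted over the list alone (adjusted p = 9e-35; adjusted p = 0.0194 with an estimated correlation), and 4 of 13 of oxidative stress defence, 7 adjusted over the list alone (adjusted p = 3.08e-09; adjusted p = 0.0194 with an estimated correlation). The anaerobic cell wall list had 2 of 8 lower, 4 adjusted over the list alone (adjusted p = 3.82e-07; adjusted p = 0.137 with an estimated correlation). The iron regulon had a median of -0.35 and a mean of 0.37 with camera on the upper side (adjusted p = 0.897). In all 122 of 6336 genes differed, 102 higher and 20 lower, and 127 without the conflicting libraries. A fit without the strain block called 78, of which 75 were among the 122. The count was 25 without hap1, 66 without hap1 rox1 mot3 and 187 without upc2 ecm22.

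Strains lacking subunits of the Hap2/3/4/5 complex, an activator of respiration genes, had lower RIP1 at 0 min. RIP1, the Rieske subunit of complex III (chromosome V, 107260 to 107907), was at 30.0 ± 3.5 CPM (n = 5) against 61.0 ± 6.3 CPM (n = 8), a log2 difference of -0.98 (SE 0.128, adjusted p = 0.00315). Other splits of the strains, given further on, did not exclude chance for this comparison. COX4 was lower, 16.8 ± 2.1 against 47.2 ± 17.4 CPM (-1.38, adjusted p = 0.0417), and the iron-siderophore mannoprotein gene FIT2 higher, 77.8 ± 35.7 against 25.5 ± 12.2 CPM (1.73, adjusted p = 0.0417). Of 22 respiratory chain genes 2 were called lower, 10 lower and 1 higher adjusted over the list alone (adjusted p = 7.08e-19; adjusted p = 0.0059 with an estimated correlation). None of 13 ATP synthase genes was called by edgeR, 6 adjusted over the list alone (adjusted p = 1.54e-09; adjusted p = 0.0204 with an estimated correlation). The iron regulon had 1 of 15 called, 6 adjusted over the list alone (adjusted p = 5.7e-10; adjusted p = 0.0431 with an estimated correlation, and adjusted p = 0.134 with an estimated correlation without the conflicting libraries).

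For the change over hypoxia, RIP1 differed by 1.31 (SE 0.191, adjusted p = 0.0093), at 15.7 ± 4.0 against 12.8 ± 1.8 CPM in late hypoxia. It was the only gene called among 6336. Of the respiratory chain 16 were higher adjusted over the list alone (adjusted p = 1.9e-34; adjusted p = 0.00136 with an estimated correlation). The late sum of hap2 hap3 hap4 hap5 includes its 180 min library, in which DAN1 (22.6 CPM, 22.4 at 0 min) and ANB1 (12.4 CPM, 8.1 at 0 min) stood near their 0 min levels, and its 240 min library, with a slope of 0.637 against the changes of the other strains. Without both, and without the conflicting libraries, RIP1 was still the only gene called, with 1.16. The reference again holds the course labelled dsc1. At 0 min 3 of 5855 genes were called (398 at an unadjusted p under 0.05), and 5 without the conflicting libraries. Leaving out 1 strain gave 1 for tpa1 ett1, hap2, hap3, hap5, hap2 hap3 hap4 hap5, dsc2, dsc3, dsc1 dsc2 dsc3 dsc5, tpa1 and ett1, 5 for mot3 and rox1 and 7 for rox1 mot3. The response count was 4 without any of upc2, mga2, ecm22 or upc2 ecm22.

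Upc2 activates sterol and anaerobic genes. Its term set upc2 and upc2 ecm22 against ecm22 and mga2, so the only strain lacking MGA2 was 1 of the 2 compared. With the spread of all libraries, the response differed for 1 of 6336 genes, AIM44 (1.39, SE 0.224, adjusted p = 0.0394), at 119 ± 4.3 CPM in late hypoxia (n = 2) against 62.0 ± 9.3 (n = 2). In mga2, AIM44 lay outside the range of the other strains, at 171 CPM at 0 min (others 68.9 to 113 CPM) and 55.5 CPM in late hypoxia (others 68.6 to 125 CPM). Leaving out the conflicting libraries gave 6 of 6326. Among them TIR4 (chromosome XV, 344335 to 345798) was at 38.8 ± 6.4 against 1173 ± 453 CPM (-4.16, SE 0.542, adjusted p = 0.00374), PBI1 at 97.7 ± 118 against 1248 ± 502 CPM (-4.33, adjusted p = 0.0118) and the fatty acid elongase gene ELO1 higher by 2.09. In late hypoxia mga2 also lay outside the other strains for ELO1 (16.7 CPM, others 89.7 to 329 CPM) and PBI1 (1604 CPM, others 14 to 893 CPM). DAN1 was not called in either fit (adjusted p = 0.504 over all libraries), with 92.3 ± 126 CPM in late hypoxia against 1832 ± 1394 CPM. It stood at 181 CPM in upc2 and 3.2 CPM in upc2 ecm22. No gene of the anaerobic cell wall list was called by edgeR over all libraries and 3 of 8 adjusted over the list alone (adjusted p = 1.38e-08; adjusted p = 0.37 with an estimated correlation). When the conflicting libraries were left out it was 1, and 7 adjusted over the list alone (adjusted p = 8.67e-15; adjusted p = 0.0467 with an estimated correlation).

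At 0 min UPC2 itself (0.6 against 51.8 CPM; chromosome IV, 889751 to 892492) was the only gene called for upc2, with 105 at an unadjusted p under 0.05. The response count was 0 without any of hap1, hap2, hap3, hap4, hap5, hap1 rox1 mot3, dsc2, dsc3, dsc5, dsc1 dsc2 dsc3 dsc5, tpa1 or ett1, 2 without tpa1 ett1, mot3 or rox1, 3 without hap2 hap3 hap4 hap5, 6 without dsc1, 341 without upc2, 342 without mga2, 151 without ecm22 and 166 without upc2 ecm22. With 4 SW strains, leaving out 1 leaves a lone strain in an arm, which is assumed to vary like the others. The 0 min count was 2 without ecm22 or upc2 ecm22.

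Strains lacking Ecm22, a second sterol regulator (ecm22 and upc2 ecm22, set against upc2 and mga2), had lower ERG4 at 0 min, 165 ± 15.8 CPM (n = 2) against 528 ± 74.6 CPM (n = 2), a log2 difference of -1.68 (SE 0.272, adjusted p = 0.0119), and ERG5 was at 78.6 ± 68.6 against 250 ± 22.1 CPM (-2.00). Of the environmental stress genes 3 of 20 were called higher, among them HXK1 (76.3 ± 4.7 against 14.1 ± 2.1 CPM, 2.44, SE 0.485, adjusted p = 0.0306) and TSL1 (1.95). Genes called lower included the short genes DYN2 (-2.74), RPL41A (-2.50), VMA9 (-2.35) and RPL39 (-1.88). Adjusted over the list alone, 8 environmental stress genes were called (adjusted p = 6.13e-08; adjusted p = 0.273 with an estimated correlation). Ribosomal protein genes had 8 of 132 lower, 16 adjusted over the list alone (adjusted p = 1.31e-08; adjusted p = 0.351 with an estimated correlation), and ergosterol 2 of 25, 4 adjusted over the list alone (adjusted p = 0.0409; adjusted p = 0.81 with an estimated correlation). Genes called lower had a median length of 554 bases and those called higher 2775, against 1245 for all genes.

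For ecm22 47 of 5855 genes were called, 23 higher and 24 lower, 181 without the conflicting libraries and 21 after a trend of read count with gene length was removed from each library. Leaving out 1 strain gave 78 for hap1, 79 for hap2, 19 for hap5, 81 for hap1 rox1 mot3, 174 for rox1 mot3, 21 for dsc2 and dsc5, 24 for dsc1 dsc2 dsc3 dsc5, 26 for tpa1, 2 for upc2 and upc2 ecm22, and 3 for mga2 and ecm22. The response differed for 0 of 6336 genes by edgeR (332 at an unadjusted p under 0.05; 11 by DESeq2), and for 1 without hap2 hap3 hap4 hap5, 295 without upc2, 55 without mga2, 57 without ecm22 and 294 without upc2 ecm22.

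DSC ligase mutants were compared with strains lacking TPA1 or ETT1. The DSC group is by label, and 1 of its 5 strains, labelled dsc1, held TUL1. At 0 min BSC1 was at 170 ± 55.8 CPM in the 5 strains labelled as DSC deletions against 36.6 ± 7.8 CPM in the other 3, higher by 2.22 (SE 0.373, adjusted p = 0.0218). HMT1, for a protein arginine methyltransferase, was at 1673 ± 535 against 474 ± 274 CPM (1.82, SE 0.409, adjusted p = 0.0489). ISD11, an iron-sulfur cluster gene (chromosome V, 250718 to 251002), was at 20.3 ± 4.6 against 77.5 ± 27.8 CPM (-1.93, SE 0.367, adjusted p = 0.0284). RPL41B (-1.75), SBH1 (-1.68) and HSP10 (-1.33) were lower as well. ISD11 was also at 102 to 116 CPM in upc2, ecm22 and upc2 ecm22 and 66.1 CPM in the library labelled rox1 mot3. In that library TUL1 was at 0.0 CPM, so a DSC subunit was missing there although it is outside the DSC group. Its ISD11 level lay nearer that of the strains lacking TPA1 or ETT1. Of the ribosomal protein genes 8 of 132 were lower, 44 adjusted over the list alone (adjusted p = 2.45e-17; adjusted p = 0.176 with an estimated correlation). Respiratory chain genes had 1 of 22 lower, 7 adjusted over the list alone (adjusted p = 0.00019; adjusted p = 0.407 with an estimated correlation).

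In this comparison 39 of 5855 genes were called, 14 higher and 25 lower. The DSC side holds the library labelled dsc1, in which TUL1 was present, and without the conflicting libraries 106 were called. With the length trend removed 4 remained. Leaving out 1 strain gave 0 for tpa1 ett1, ett1, dsc2, dsc3 and dsc5, 14 for dsc1 and dsc1 dsc2 dsc3 dsc5, 63 for mot3 and rox1, 92 for tpa1 and 186 for rox1 mot3. No response differed by edgeR (155 genes at an unadjusted p under 0.05; 0 by DESeq2).

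Only 1 strain lacked MGA2 (chromosome IX, 416124 to 419465), so its values have no replicate check. IZH4, a membrane protein gene, was at 5.3 CPM at 0 min where the other 21 strains held 15.5 to 313 CPM, and at 6.9 CPM in late hypoxia against 440.1 to 1890 CPM. OLE1 was at 1022 CPM at 0 min, within the range of the others (854 to 7372), and at 113 CPM in late hypoxia, below their 5013 to 12594. By the size rule 2 genes, MGA2 and IZH4, were lower and 0 higher; the same rule gave 5 genes for upc2, 4 for tpa1, 3 for upc2 ecm22 and 0 for each of the other 18 strains.

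**Figure D3:**
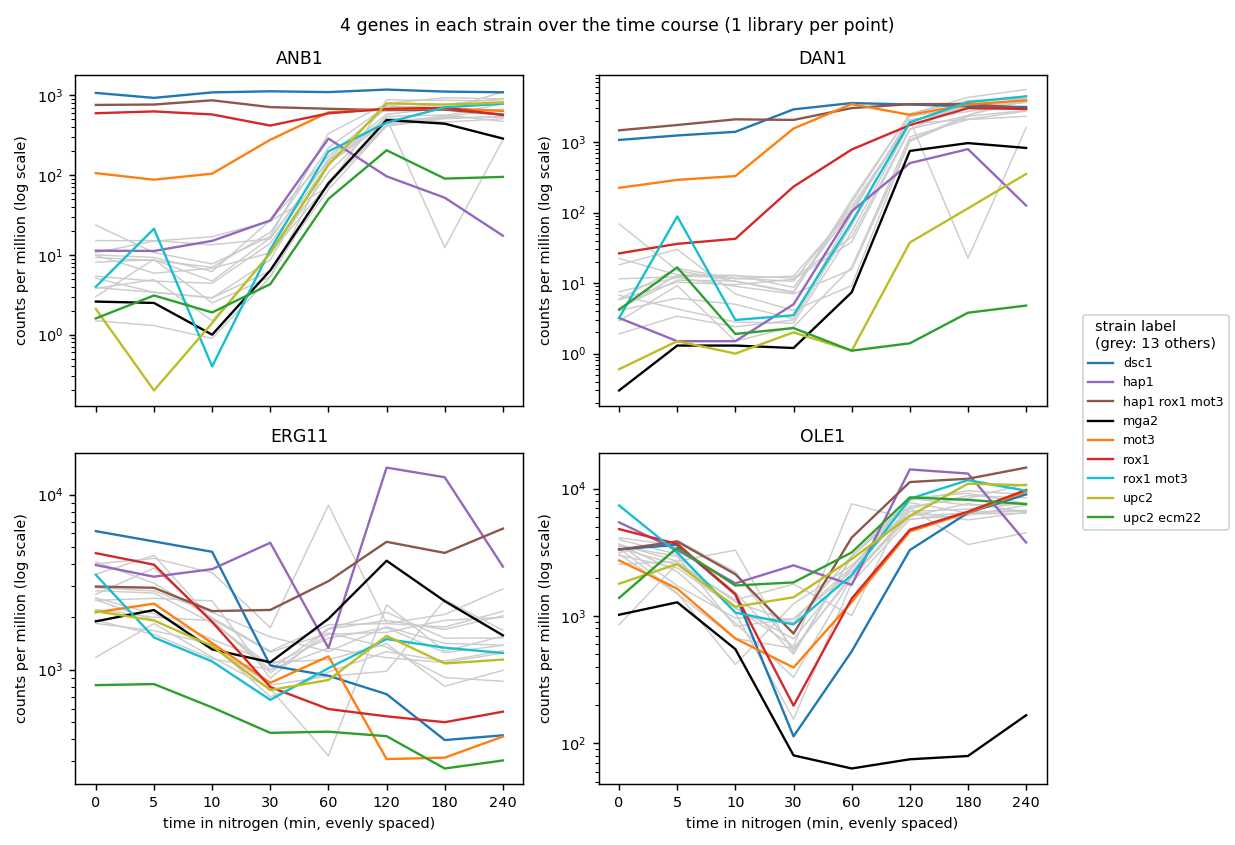
Levels in CPM (log axis) of ANB1, DAN1, ERG11 and OLE1 against time in nitrogen in min, evenly spaced, with 1 line per strain label and 1 library per point; 9 labels are coloured and 13 are grey. ANB1 is high at 0 min in the libraries labelled dsc1, rox1 and hap1 rox1 mot3, DAN1 stays low in upc2 ecm22, and OLE1 is lowest from 30 min on in mga2.

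**Figure D4:**
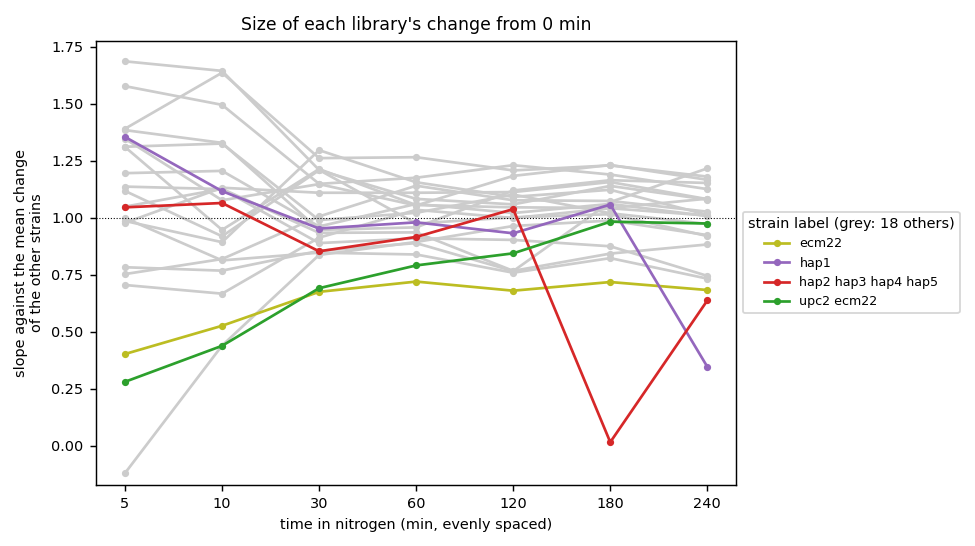
Slope of each strain's log2 changes from 0 min against the mean changes of the other strains, over the genes called at each time, without strains of conflicting label in that mean (vertical axis), against time in nitrogen in min, evenly spaced; 1 line is 1 strain label, 4 are coloured and 18 grey. The strain hap2 hap3 hap4 hap5 stands at 0.015 at 180 min and 0.637 at 240 min, and the library labelled hap1 at 0.346 at 240 min.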

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

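Tests of labels, of the late response of hap2 hap3 hap4 hap5 and of gene length were chosen after the results were seen; the counts over other splits of the samples were planned.

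In the courses labelled dsc1 and rox1 mot3 the deleted genes went against the label at all 8 times. Of 89 genes called for rox1 or mot3 without the conflicting libraries, 95.5% lay on the called side in the library labelled dsc1 at 0 min, against 58.4% in the library labelled rox1 mot3 and 32.6% to 70.8% in the other reference strains. A mixture of both strains in each course is argued against by ROX1 and MOT3 at no more than 3.4% of their usual level under the label dsc1, with TUL1 no higher under the label rox1 mot3. Under the label dsc1, TUL1 stood at 83.1% to 123.4% of its usual level, and under the label rox1 mot3 at no more than 1.2%. Transcripts of a deleted gene at its usual level argue against a biological effect in strains as labelled. An exchange of the 2 labels may account for the pattern. The 60 min library labelled hap1 held HAP1 at 322.6 CPM. That library entered the fit at 60 min under its label, and no strain comparison at 0 min or in late hypoxia uses it.

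The 180 min library of hap2 hap3 hap4 hap5 had a slope of 0.015 against the changes of the other strains, and its 240 min library one of 0.637. Loss of the HAP complex as the cause is argued against by a median slope of 1.107 at 180 min in the 4 single deletions, where the reference strains ran from 0.875 to 1.232. A slow response throughout is argued against by its slope of 1.038 at 120 min, above the lowest reference slope of 0.903. Both lowest values belong to the conflicting course labelled dsc1. Apart from it the lowest reference slopes were those of tpa1 ett1, 0.988 at 180 min and 0.964 at 120 min, also under the values compared. For the 180 min library alone, little or no hypoxia under that label is a candidate explanation: its r across genes with the 0 min library was 0.988, against 0.959 with 120 min and 0.968 with 240 min, and at most 0.956 with 0 min in other strains. Genes are not independent replicates, that explanation leaves the 240 min library unaccounted for, and a change in the strain or its culture after 120 min stays open and untested.

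Genes called lower at 0 min were short, with a median length of 521.5 bases for DSC against TPA1 ETT1 and 554 for ecm22, against 1245 for all genes, while Spearman's rho of the fold with length across all genes was 0.121 and 0.522, and -0.435 for mot3, -0.326 for rox1, 0.186 for hap1 and -0.142 for the HAP complex, for which no correction was run. For ecm22 a difference in length bias between libraries may account for part of the calls: 21 genes were called after the trend was removed, and of 44 called genes with a length 17 were still called. In the 27 that ended, the median size went from 1.24 (SE 0.269) to 0.85 (SE 0.247), so the folds shrank. For DSC against TPA1 ETT1, 4 were called after removal; in the 34 that ended, the median size went from 1.03 (SE 0.205) to 0.89 (SE 0.224) and adjusted p was at least 0.0755 with a median of 0.0873, so calls near the threshold ended with a lower median fold and a wider median SE. There the median fold fell by less than its SE while the count dropped, so length and a difference between the strains cannot be told apart, and an effect of the deletions stays open and untested for both.

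Dixon's test was run 120 times, on 20 lists and 2 measures in the same 3 groups of strains, and marked 8. Chance marks about 1 in 20, so the total of 8 is near what chance gives, but 4 of the 8 fell on 1 course, labelled dsc1. The tests share strains and are not independent, so the total says little about single marks. Among the DSC strains the course labelled dsc1, which lacked ROX1 and MOT3, was marked for its change at 240 min in 4 lists, with medians of 1.26 for anaerobic cell wall genes, -1.27 for oxidative stress defence, 1.97 for the PAU family and 0.34 for Rox1-repressed genes. Among the HAP deletions, hap2 hap3 hap4 hap5 was marked with -0.23 for the respiratory chain and -1.15 for ribosome biogenesis. Among the SW strains, mga2 was marked with 0.84 for hexose transport at 240 min. The mark on ecm22, with a PAU level of -1.78 at 0 min, is void, because the other 3 SW strains were tied at the floor of -4.45 and any value above it would be marked. By a test of the difference itself, the response differed between strains with and without the deletion for 122 genes with hap1, 1 with the HAP complex and 1 with upc2.

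Other splits of the samples were counted for each comparison with at least 3 strains on each side, the real one included. For the time course, a split swapped 0 min and the later time in strains drawn at random. There, 1 of 60 splits gave as many genes at each of 5, 30, 120 and 240 min (real counts 207, 1287, 815 and 1284, highest other 0 at each). The real direction stood apart from the swapped ones. A response shared by the strains cancels under such swaps, and 60 splits allow no share under 1.7%, so these counts alone do not exclude chance. For DSC against TPA1 ETT1 at 0 min, 1 of 56 splits gave as many (real count 39, highest other 0), so the grouping as labelled stood apart. That grouping holds the library labelled dsc1, in which TUL1 was present, and leaves out the library labelled rox1 mot3, in which TUL1 was near 0. The splits therefore do not decide whether loss of DSC subunits is behind the calls. For the HAP complex, 2 of the 100 splits drawn at 0 min gave as many genes (real count 3, highest other 420). In the response it was 2 of 60 (real count 1, highest other 345). So few real calls, against 1 other split with far more, do not exclude chance. In each case only 1 other split gave any call, and the second highest gave 0. At 0 min that split set dsc1, hap2 hap3 hap4 hap5, hap4, hap5 and tpa1 against the rest, and in the response dsc1 dsc2 dsc3 dsc5, dsc2, dsc3, dsc5 and hap3. Why these splits called so many genes was not tested.

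For the groups as labelled, chance cannot be excluded for rox1 at 0 min, where 12 of 100 splits gave as many genes (real count 1, highest other 21, for dsc1, rox1 and tpa1 ett1). Nor can it for mot3 at 0 min, with 8 of 100 (real count 3, highest other 26, for dsc1, mot3 and tpa1 ett1). Both real groups held the library labelled rox1 mot3, in which ROX1 and MOT3 were present. These splits therefore do not judge strains that lacked ROX1 or MOT3. In both, the highest split put the course labelled dsc1, which lacked ROX1 and MOT3, on the side of the deletion, and it called several times the real count. With a real count of 0 in the response, all splits gave as many genes: 60 of 60 for rox1 (highest other 4), 60 of 60 for mot3 (highest other 164) and 56 of 56 for DSC against TPA1 ETT1 (highest other 337). The second highest counts there were 0 for rox1, 4 for mot3 and 1 for DSC against TPA1 ETT1, so each high count came from 1 split, and its cause was not tested. Splits were made on all libraries, the conflicting ones included.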

How the results depend on the processing

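Fits without the conflicting libraries, without the 180 and 240 min libraries of hap2 hap3 hap4 hap5, and with a length trend removed were tests chosen after the results were seen; the others were planned. RLE factors moved no count of genes by over 1.5 times. In the 4 SW strains alone, 37 genes were called at 5 min, 415 at 120 min and 546 at 240 min, with fewer samples, and 0 for the upc2 response. There BSC1 (0.32), PRM7 (0.29) and DBP2 (0.26) at 5 min, PAU2 at 30 min (-1.60) and 120 min (-0.79) and FAA1 at 240 min (0.069) had the opposite sign. The time fit with no replicate block gave PAU2 -0.018 at 30 min, and the hap1 response 78 genes; the strain block changed no other count by over 1.5 times.

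DESeq2 called, at 0 min, 29 genes for the HAP complex, 228 for DSC against TPA1 ETT1, 5 for rox1, 17 for mot3, 37 for hap1, 3 for upc2 and 348 for ecm22, and in the response 8 for the HAP complex, 1 for rox1, 207 for hap1, 25 for upc2 and 11 for ecm22. Without the conflicting libraries the 0 min counts were 5 for the HAP complex, 106 for DSC against TPA1 ETT1, 35 for rox1, 61 for mot3, 22 for hap1 and 181 for ecm22, and the response counts 2 for rox1 and 6 for upc2; without the late hap2 hap3 hap4 hap5 libraries as well they were 2 and 12. With a length trend removed they were 4 for DSC against TPA1 ETT1 and 21 for ecm22 at 0 min. The upc2 response was 2 with no filter, 3 with lane 1 alone and 7 with 240 min alone as late hypoxia. In the NH strains alone the HAP response was 4 and the hap1 response 190. Of gene list tests of the strain terms and of 5, 30, 120 and 240 min over all libraries, 16 passed with an estimated correlation, against 123 with the preset one; the tests at 10, 60 and 180 min are not in that count. Where no cause is named, the cause was not tested.

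Leaving out 1 strain at a time moved the 0 min counts over 1 to 7 for the HAP complex, 0 to 186 for DSC against TPA1 ETT1, 0 to 9 for rox1, 0 to 27 for mot3, 6 to 12 for hap1, 1 to 2 for upc2 and 2 to 174 for ecm22. Response counts ran over 1 to 4 for the HAP complex, 0 to 1 for rox1, 25 to 187 for hap1, 0 to 342 for upc2 and 0 to 295 for ecm22, and were 0 throughout for DSC against TPA1 ETT1 and mot3. Of 4816 values of named genes under the alternatives, 4211 kept direction and side of the threshold and 598 kept only the direction. The 4 SW strains alone at 0 min were not run, since 1 residual degree of freedom is left. Depth limits genes near 0, such as the PAU family at 0 min.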

Other observations

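The values here were chosen after they were seen. In mga2, late hypoxia left several metabolic and stress genes outside the range of the other 21 strains. ELO1, for fatty acid elongation, was at 16.7 CPM against 89.7 to 329 CPM, ACC1 at 2241 against 4697 to 15326 CPM and HMG2 at 134 against 385 to 952 CPM. Above the range were the stress gene HSP12 at 3846 (34.8 to 1028 CPM), HXK1 at 1121 (149 to 468 CPM), GPH1, for glycogen breakdown, at 909 (143 to 461 CPM) and KAR2, the ER chaperone, at 5495 (1107 to 3028 CPM). It is 1 strain, with no replicate check.

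ISD11 at 0 min was at 102 to 116 CPM in upc2, ecm22, upc2 ecm22 and tpa1 ett1, at 78.4 in mga2, 77.3 in ett1, 66.1 in the library labelled rox1 mot3 and 49.8 in tpa1. In the other 14 strains it was at 11.6 to 28.4 CPM. It lies beside TPA1 on chromosome V (R64, ISD11 250718 to 251002, TPA1 251728 to 253662). Reads aligned to several places per 100 gene reads at 0 min were 169.2 in the library labelled dsc1 and 54.5 in the library labelled rox1 mot3, the highest and the lowest of the 18 NH strains.

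ERG11 was at 8711 CPM in the 60 min library labelled hap2, in which HAP1 was at 1.79 CPM, and at 1329 CPM in the 60 min library labelled hap1.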
